A study of Mus musculus with 12 samples.

How the data were processed

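Total RNA of sorted thymic pre-T cells was sequenced in 12 libraries, with 4 biological replicates in each of 3 groups: DN3a and DN3b cells of control mice, and DN3-like cells of mice lacking both Zfp36l1 and Zfp36l2 (DCKO). Per the labels, RNA was purified with the RNeasy Micro kit and made into stranded libraries after ribosomal RNA removal. The submitters' processing notes name Trim Galore, TopHat2 2.0.12, HTSeq and DESeq2 1.6.3 and the genome build GRCm38; the annotation release and the strand setting are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart, and reads of near-identical genes can be split or lost. The authors deposited a table of raw counts per Ensembl gene, whole numbers with 1 column per library, and every value reported here was computed from it unless the authors' tables are named. A further table deposited by the authors holds a signal per gene and library, the counts divided by 1 size factor per library; its ratio to the raw counts was constant in each column, and it was used only for that check. The authors' deposited DESeq2 tables, 1 per pair of groups, hold log2 fold changes with standard errors, a Wald score, and p-values with adjusted p-values. These were used only for the counts of genes set beside the counts obtained here.

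The table held 43629 genes, of which 42462 had a symbol in GENCODE release M21 (GRCm38) and 1167 did not. Libraries held 28479157 to 45975678 counts, and no pair of replicates of a group was alike within counting noise (chi-square per degree of freedom from 33.5 upward). Counting error is small at this depth for most genes, and PCR copies are not separated from independent molecules, so spreads between replicates rather than counting intervals are given. Genes were kept with edgeR's filterByExpr (count minimum 10), which left 13944. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. All 12 libraries entered 1 edgeR quasi-likelihood fit with group as the only term and TMM factors, leaving 9 residual degrees of freedom; the 3 contrasts were tested two-sided, and Benjamini-Hochberg adjustment was made over all genes within a contrast, with 0.05 as the threshold. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM on TMM-scaled library sizes, as mean and SD over 4 libraries; adjusted p-values in the text are from edgeR for genes and from camera for lists. Folds are the antilog of the fitted log2 fold change.

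Gene lists (29) were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over the lists of a contrast, and again with the correlation estimated from the data and with fry. Camera compares the genes of a list with the other genes; fry's directional test asks whether a list's genes move, on balance, in 1 direction. Members were counted as up or down by the adjusted p over all genes and again adjusted over the list alone; where the second count is not printed beside a called list, it was the same. The lists cover DNA damage response, p53 targets, G1 and S phase, G2 and M phase, cell cycle inhibitors, Notch signalling, the T cell receptor complex, beta-selection activation genes, V(D)J recombination, T lineage transcription factors, early progenitors, CD4 and CD8 expressing thymocytes, gamma-delta T cells, B cells, myeloid cells, dendritic cells, cytotoxic lymphocytes, erythroid cells and platelets, thymic stroma, immediate early and AU-rich transcripts, the BCL2 family, interferon response, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, ribosome biogenesis, replication-dependent histones and T cell receptor beta segments. The lists, the comparisons, the naming rule and most alternatives were fixed before the data were examined, by someone who knew the published account of these mice; the lists for DNA damage, p53 and the cell cycle were chosen with that knowledge. Some genes stand in more than 1 list.

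Named genes follow a rule: Zfp36l1, Zfp36l2 and Zfp36; per comparison the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between the libraries of the groups, without predicted genes, pseudogenes, small RNA, mitochondrial and receptor segment genes; up to 3 members of each list with the smallest adjusted p; and a fixed set of stage and cycle genes. Which of the list members stand in the text as examples was chosen after their values were seen, as were Malat1, Rn7sk, Gm26917, Lars2, Gm42418, H2-Q1 and the feature with 9.02% of the counts in DCKO library 1. The genes of the fixed set and of the largest rises and falls are printed for each comparison, and a part of the list members; a few genes that the rule names are not reported here.

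The position of DCKO was measured on genes chosen with 2 replicate numbers of the control groups and computed on the others. Per gene, the difference of mean DCKO and DN3a log2 levels was divided by that of DN3b and DN3a, and the median over genes was taken. Replicate numbers were tested for pairing by correlating the deviations of libraries from their group means across genes: same-number DN3a and DN3b libraries gave 0.35 to 0.56, while DCKO gave -0.19 to 0.12 with DN3a and -0.26 to 0.07 with DN3b, so a blocked fit of the 8 control libraries was added for DN3b against DN3a. The longest annotated 3 prime UTR of each gene was searched for UAUUUAU, with logistic models that hold log UTR length and permutations within UTR length bins. Alternatives covered normalization (RLE, upper quartile), low-count filters, DESeq2, limma-voom, fits of 8 libraries, replicate number as a block, a stricter threshold, removal of the most abundant features, and leaving out each library. The fit was tested on simulated data with 200 changed genes among unchanged ones: 54.0% to 62.0% of 2-fold changes and 87.5% to 91.5% of 4-fold changes were recovered, and 3.45% to 8.85% of the calls were false, over the 3 comparisons. In the data 18.9% to 60.2% of genes were called, far more than were changed in the simulation, so the rates describe that setting only. No library was left out.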

Results

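RNA was sequenced from pre-T cells sorted by flow cytometry from the thymus of C57BL/6 mice, in 3 groups of 4 biological replicates. DN3a and DN3b are successive stages of thymocytes that lack CD4 and CD8, before and after beta selection, the checkpoint at which a rearranged T cell receptor beta gene must prove functional. The control groups came from mice with floxed Zfp36l1 and Zfp36l2, which encode zinc finger proteins that bind AU-rich messenger RNA. The third group, called DCKO here, held DN3-like cells of mice in which a CD2-driven Cre recombinase deletes both genes. The libraries held 28479157 to 45975678 counts in DN3a, 32359182 to 41664096 in DN3b and 30401159 to 41258922 in DCKO (levels below are in CPM, TMM-scaled). The first principal component of the log2 CPM took 52.0% of the variance and set DN3a (-88.0 to -53.0) apart from DN3b (-8.02 to 62.5) and DCKO (35.9 to 54.7). The second took 17.1% and set DN3b (22.2 to 50.7) apart from DCKO (-43.6 to -23.4). In DCKO library 1, 9.02% of the counts fell on ENSMUSG00000045999, a feature without a symbol in the annotation, and in DCKO library 2 Lars2 and Gm42418 took 0.569% and 1.14%. The nuclear RNA Malat1 took 0.698% ± 0.111 of the counts in DN3a, 0.181% ± 0.0689 in DN3b and 0.155% ± 0.0441 in DCKO (SD, n = 4). In the same order the small nuclear RNA Rn7sk took 0.756% ± 0.15, 0.364% ± 0.0842 and 0.24% ± 0.0479, mitochondrial genes 3.76% ± 0.641, 2.62% ± 0.838 and 2.08% ± 0.465, and Gm26917 0.322% ± 0.217, 0.622% ± 0.336 and 0.2% ± 0.044.

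**Figure D1:**
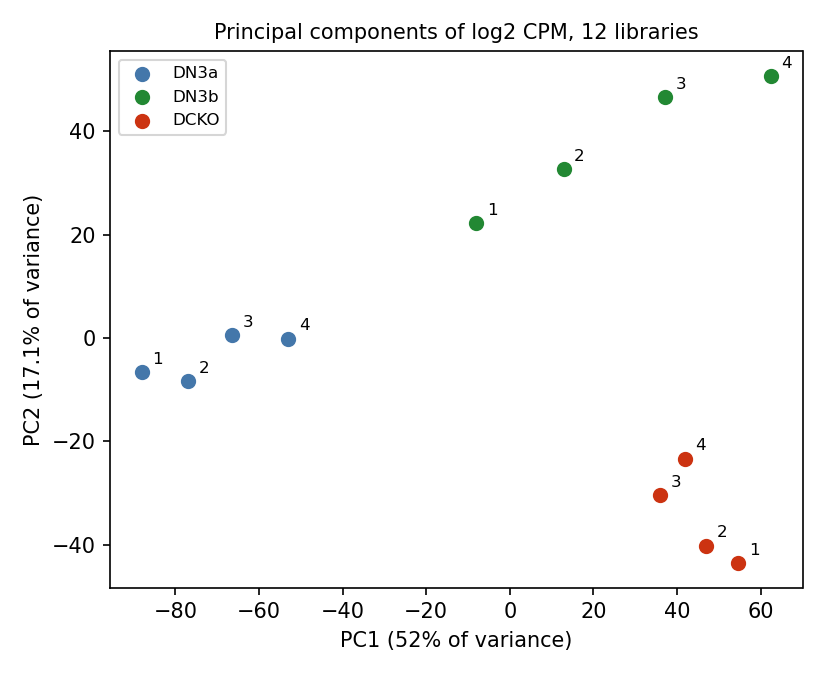
Positions of the 12 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis, coloured by group and numbered by replicate. The DCKO libraries lie between -43.6 and -23.4 on the second component, and the DN3b libraries between 22.2 and 50.7.

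Both targeted transcripts were depleted in every DCKO library. Zfp36l1 (ENSMUSG00000021127, GRCm38 chromosome 12, 80107754 to 80113013) stood at 33.9 ± 7.15 CPM in DN3a, 14.3 ± 6.13 in DN3b and 2.33 ± 1.01 in DCKO (SD, n = 4), and its highest DCKO level, 3.80, lay below its lowest DN3b level, 9.63. Zfp36l2 (ENSMUSG00000045817, chromosome 17, 84183931 to 84187947) stood at 541 ± 145, 364 ± 79.4 and 63.9 ± 20.1. In DCKO Zfp36l1 fell by 3.86 ± 0.34 (SE) on the log2 scale against DN3a (adjusted p = 4e-06) and by 2.61 ± 0.33 against DN3b (0.00021). For Zfp36l2 the log2 fold changes were -3.08 ± 0.26 (3.7e-06) and -2.51 ± 0.26 (5.1e-05). The remaining counts of both genes were not resolved by exon, since the deposited tables hold 1 value per gene. Between the control stages Zfp36l1 was 2.37-fold lower in DN3b (log2 -1.24 ± 0.30, adjusted p = 0.0039), while Zfp36l2 (-0.57 ± 0.24) reached an adjusted p of 0.064, or 0.00084 with replicate number as a block (-0.58). It also passed without DN3a library 1 (0.0165) or DN3b library 4 (0.0365) and with upper quartile scaling (0.0241), a stricter low-count filter (0.0458) or the 8 control libraries alone (0.0447). The related gene Zfp36 stood at 1.36 ± 0.71 to 2.03 ± 0.20 CPM in the 3 groups; its change in DCKO had an adjusted p of 0.13 against DN3a and 0.95 against DN3b. Against DN3a it passed without DN3a library 1 (log2 0.97, 0.00268) and with limma-voom (0.68, 0.0486). Between DN3b and DN3a it missed the threshold as well (0.58, 0.11), and passed without DN3a library 1 (0.00272) and with limma-voom (0.70, 0.0415).

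**Figure D2:**
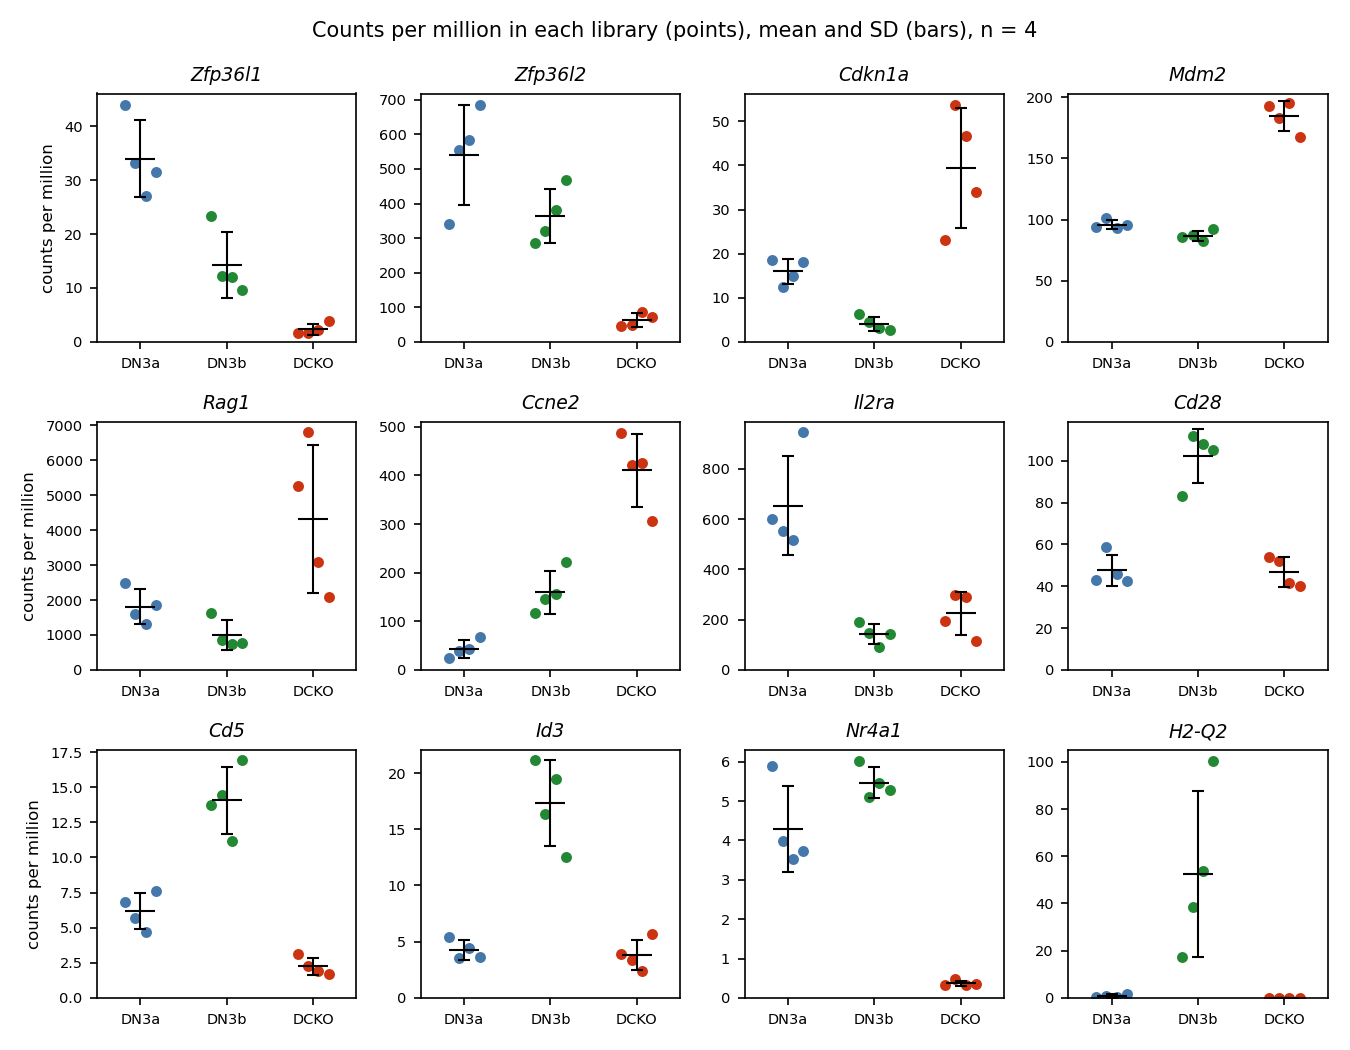
CPM of 12 genes in each library (points), with the mean and SD of each group (bars, n = 4); every axis starts at 0. Zfp36l1 and Zfp36l2 are lowest in all 4 DCKO libraries, Cdkn1a averages 39.4 in DCKO against 4.14 in DN3b, and H2-Q2 averages 52.4 in DN3b against 0.0876 in DCKO.

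The comparison of DN3b with DN3a describes the normal passage through beta selection. DN3b cells had more transcripts for the cell cycle, for ribosomes and for energy metabolism, and fewer for Notch signalling and interferon response. Each of these list calls was lost with an estimated correlation (adjusted p = 0.374 to 0.418). Of 58 measured replication-dependent histone genes 56 rose and 2 fell; Hist1h4a was higher by 3.58 ± 0.71 on the log2 scale and Hist1h4f 11.3-fold, with Hist1h4k (3.34 ± 0.75) and Hist1h2ai (3.31 ± 0.70) also among the 8 largest rises. All 30 genes of G2 and M phase rose, among them the mitotic regulator Cdc20 (log2 2.31 ± 0.28) and the kinase Aurkb (2.45 ± 0.30), and 35 of 37 genes of G1 and S phase rose while 2 fell, Ccnd2 (-1.23 ± 0.16) and Cdk6 (-0.48 ± 0.12). Cyclin E2 (Ccne2) rose 3.73-fold and the helicase subunit Mcm5 3.34-fold. All 27 genes of oxidative phosphorylation and all 24 of ribosome biogenesis rose, as did 69 of 83 ribosomal protein genes (72 adjusted over the list alone; 1 fell) and 15 of 20 glycolysis genes (16 adjusted over the list alone; 2 fell). The shares of Malat1, Rn7sk and mitochondrial transcripts, given above, were lower in DN3b. Of 30 genes of DNA damage response and repair 26 rose and 1 fell, with Rpa2 at 1.19 ± 0.12 and Parp1 at 0.92 ± 0.11.

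Markers of the stage moved as well. The coreceptor genes Cd8b1 (40.1-fold) and Cd8a (7.97-fold), the transcription factor Ikzf3 (9.60-fold), the kinase Zap70 (3.50-fold), the costimulatory receptor Cd28 (2.15-fold) and Id3 (4.07-fold) were higher in DN3b, each with an adjusted p of 0.00011 or less. The transferrin receptor Tfrc (log2 1.11 ± 0.20) and Myc (0.66 ± 0.14) rose too. Il2ra, which encodes CD25, was 4.59-fold lower, and Rag2 (2.52-fold), the Notch target Hes1 (3.18-fold), the cycle inhibitor Cdkn1a (3.84-fold) and Cdkn1b (1.43-fold) were also lower. Khdc1a, H19, Cyp2j6, Scn4b, Klhl4, Serpinb1a, Hsd11b1 and Tshz2 had the largest falls under the naming rule, from -3.82 ± 0.61 to -2.92 ± 0.59. Of the Notch list 11 of 18 genes fell (Maml2 -1.31 ± 0.20) and 1 rose, of the early progenitor list 9 of 15 fell (Cd34 -3.70 ± 0.70, on 4 counts in the 4 DN3b libraries) and 1 rose, of the T cell receptor complex list 12 of 22 fell (Cd3g -1.19 ± 0.16) and 3 rose, and of the interferon response list 20 of 26 fell (21 adjusted over the list alone; Gbp2 -1.73 ± 0.24) and 1 rose. Summed myeloid markers moved in the same direction, from 71.1 ± 2.38 CPM in DN3a to 49.1 ± 11.4 in DN3b (SD, n = 4). Cd4 (0.22, adjusted p = 0.76) and Egr1 (-0.15, 0.77) missed the threshold. Rag1 (-0.86, 0.057) and Trp53 (0.45, 0.054) missed it too, but had adjusted p of 0.000156 (-0.93) and 0.00358 (0.42) with replicate number as a block. Rag1 also passed without DN3b library 1 (-1.20, 0.010), DCKO library 2 (0.0378) or DCKO library 4 (0.0329), and with DESeq2 (0.0282) or limma-voom (0.0386). Trp53 also passed without DN3a library 4 (0.0432), DN3b library 1 (0.0223), DCKO library 1 (0.0270) or DCKO library 4 (0.0466). Ptcra (-1.13, 0.036) and Notch1 (-0.69, 0.043) passed; without DN3a library 1 they stood at -0.74 (0.13) and -0.39 (0.156). With the 8 control libraries alone neither passed (0.0579 and 0.0671). Ptcra also lost the call without DN3b library 2 (0.0895), 3 (0.0944) or 4 (0.0917) and moved to -1.77 without DN3b library 1. Notch1 also lost it without DN3a library 4 (0.0514), DN3b library 2 (0.105), 3 (0.0992) or 4 (0.103), or DCKO library 3 (0.0501). Cd27 (-0.49, 0.018) lost the call without DN3b library 4 (0.0524), and Notch3 (-1.61, 0.018) without DN3a library 1 (0.0605) or DN3b library 3 (0.0514), while it moved to -2.50 (0.000128) without DN3b library 1. Ccnd3 (0.51, 0.038) lost it without DN3a library 2 (0.110), 3 (0.0585) or 4 (0.0966), DN3b library 1 (0.0681), 3 (0.0708) or 4 (0.0971), or DCKO library 3 (0.0572), and with upper quartile scaling (0.119) or a stricter low-count filter (0.0584).

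Of 13944 genes tested, 7334 passed an FDR of 0.05 in this comparison, 3815 higher and 3519 lower in DN3b, 2734 of them by at least 2-fold. Upper quartile scaling moved the median of all genes from -0.022 to -0.167 and the split to 3021 higher and 4536 lower. Replicate numbers paired the DN3a and DN3b libraries (correlations of 0.35 to 0.56 within numbers), and a fit of the 8 control libraries with number as a block called 9233 genes, 4529 higher and 4704 lower, 7251 of them among the 7334 and in the same direction. Camera called 12 of 29 gene lists, the 8 higher and 4 lower ones described above, with adjusted p from 1.22e-14 (histones) to 0.0176 (T cell receptor complex); with an estimated correlation none passed, with adjusted p = 0.374 to 0.418 for these 12. The other 17 lists had adjusted p from 0.088 to 0.908, and for beta-selection activation genes 10 of 20 rose and 3 fell (0.088; adjusted p = 0.374 with an estimated correlation). Fry called this list higher in DN3b (adjusted p = 9.65e-06).

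DCKO cells were compared with DN3a, the stage that precedes beta selection. All 30 genes of G2 and M phase rose, 35 of 37 of G1 and S phase rose and 2 fell, and 47 of 58 histone genes rose (48 adjusted over the list alone) and 0 fell. Cyclin E1 (Ccne1) rose 11.6-fold, Ccne2 9.56-fold and the ribonucleotide reductase subunit Rrm2 9.34-fold, and the S phase regulators E2f2 and Cdc25a rose 4.71-fold and 2.78-fold. All 27 genes of oxidative phosphorylation and all 24 of ribosome biogenesis rose, as did 62 of 83 ribosomal protein genes (64 adjusted over the list alone; 1 fell), 14 of 20 glycolysis genes (15 adjusted over the list alone; 2 fell; Hk2 5.03-fold) and 25 of 30 genes of DNA damage response and repair (2 fell; Rpa2 2.35-fold, Fancd2 4.21-fold). Of 22 genes of cholesterol synthesis 15 rose and 2 fell (Fdps 3.84-fold, Hsd17b7 3.19-fold, Insig1 2.14-fold). Each of these lists lost its call with an estimated correlation (adjusted p = 0.544), and the shares of Malat1, Rn7sk and mitochondrial transcripts were lower in DCKO than in DN3a. Coreceptor genes Cd8b1 (13.1-fold) and Cd8a (6.50-fold) and Tfrc (3.06-fold) were higher, and Il2ra (2.91-fold), Cd27 (1.85-fold) and Ccnd2 (2.46-fold) lower. Cdkn1a rose 2.47-fold and Mdm2 1.93-fold. The immediate early genes Egr1 (12.7-fold) and Nr4a1 (11.4-fold) fell, while Cd28 (log2 -0.02 ± 0.14, adjusted p = 0.92) and Id3 (-0.16 ± 0.26, 0.60) missed the threshold. The vascular cadherin gene Cdh5 (30.1-fold), Bcat1 (11.9-fold), Pbk (log2 3.09 ± 0.33) and Cdr2 (2.97 ± 0.34) were among the largest rises, and Klhl4 (63.2-fold), Arrdc4 (20.9-fold), Cdh23 (18.1-fold), Neb (14.2-fold), Dennd2d (13.5-fold), Rxfp1 (log2 -3.59 ± 0.44) and Tshz2 (-3.55 ± 0.61) among the largest falls.

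Against DN3a, Rag1 (log2 1.25 ± 0.36, adjusted p = 0.0088), Ccnd3 (0.65 ± 0.19, 0.010) and Myc (0.40 ± 0.14, 0.025) were higher in DCKO, and Cdk6 (-0.37 ± 0.12, 0.017) and Notch3 (-1.36 ± 0.51, 0.034) lower. Myc lost the call without DN3a library 2 (0.0756) or 3 (0.0707) or DCKO library 2 (0.0629) or 4 (0.0730), and Notch3 without DN3a library 1 (moved to -0.90, 0.124) or DCKO library 1 (0.0628), 3 (0.0759) or 4 (0.0627). With upper quartile scaling Myc (0.18, 0.263) and Ccnd3 (0.43, 0.0639) no longer passed, nor did Myc with a stricter low-count filter (0.0582) or the 8 libraries of the comparison alone (0.0591). Without DCKO libraries 1 and 2 together Rag1 moved to 0.50 (0.247) and Cdk6 to -0.21 (0.147), and these and Notch3 (-1.54, 0.10) no longer passed. Ptcra (-0.49, 0.32), Rag2 (-0.05, 0.89), Cd4 (-0.28, 0.69), Notch1 (-0.58, 0.074), Hes1 (-0.57, 0.20), Cdkn1b (-0.20, 0.13) and Trp53 (0.35, 0.12) missed the threshold. With the 8 libraries of the comparison alone Hes1 (-0.62, 0.00591) and Notch1 (-0.62, 0.0408) passed. Notch1 also passed without DN3b library 1 (0.0325) or DN3a library 2 (0.0375) and with upper quartile scaling (0.0172). Hes1 passed also without DN3b library 1 (0.0309), Cdkn1b without DCKO library 3 (0.0292) and Trp53 without DCKO library 1 (0.0272). Without DCKO libraries 1 and 2 together Cd4 (-1.79, 0.0208) and Trp53 (0.59, 0.0154) passed. Cdkn1b also passed with upper quartile scaling (-0.42, 0.00664).

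In this comparison 8391 of 13944 genes passed, 4275 higher and 4116 lower in DCKO, 3698 by at least 2-fold. Upper quartile scaling moved the median of all genes from -0.041 to -0.264 and the split to 3119 higher and 5528 lower. Camera called 10 lists, 9 higher and T cell receptor beta segments lower (21 of 41 fell, 3 rose; Trbv1 -3.39 ± 0.30), with adjusted p from 5.27e-12 to 0.00242; with an estimated correlation none passed (adjusted p = 0.544 for each). The other 19 lists had adjusted p from 0.0503 (Notch signalling, 10 of 18 fell and 2 rose) to 0.986. The Notch list passed without DN3b library 1 (0.0308), DN3a library 2 (0.0398), DN3a library 3 (0.0354) or DCKO library 2 (0.0366). Fry called it lower (adjusted p = 0.00135).

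Set against DN3b, the stage that follows beta selection, DCKO cells had lower levels of 9 of 20 measured beta-selection activation genes (0 rose; 11 fell and 1 rose adjusted over the list alone) and higher levels of Cdkn1a, Mdm2 and the recombinase genes. From DN3a to DN3b 10 of the 20 rose and 3 fell. In DCKO against DN3a 5 of the 20 rose and 9 fell (camera adjusted p = 0.36), and fry called the list lower (adjusted p = 1.69e-05). The early activation genes Nr4a1 and Egr1 were 14.5-fold and 11.5-fold lower, the surface receptor Cd5 6.28-fold, Id3 4.55-fold and Cd28 2.17-fold. Egr1 rested on 23 counts and Nr4a1 on 49 in the 4 DCKO libraries together. Egr1 averaged 2.24 ± 0.698 CPM in DN3a and 2.01 ± 0.344 in DN3b, and Nr4a1 4.29 ± 1.09 and 5.47 ± 0.399 (SD, n = 4). Both fell in DCKO against DN3a as well, so these falls go beyond any rise from DN3a to DN3b. Cd6 (13.5-fold), the kinases Zap70 (4.09-fold) and Matk (6.05-fold), the pseudokinase Trib2 (14.1-fold) and Ikzf3 (9.16-fold) were lower, and Cd3g was 2.40-fold higher; the T cell receptor complex list had 3 genes up and 3 down of 22 (adjusted p = 0.577). Il2ra (0.66 ± 0.30, adjusted p = 0.14), Cd27 (-0.40, 0.089), Tfrc (0.51, 0.094), Myc (-0.26, 0.21), Ccnd2 (-0.07, 0.80), Cd8a (-0.29, 0.58), Hes1 (1.09, 0.058), Trp53 (-0.10, 0.73), Notch1 (0.11, 0.80), Notch3 (0.26, 0.76), Cd4 (-0.50, 0.57), Ccnd3 (0.14, 0.64), Cdk6 (0.11, 0.53) and Cdkn1b (0.32, 0.051) missed the threshold. Hes1 passed without DN3b library 1 (1.74, 0.00050) and with DESeq2 (0.0148), limma-voom (0.0194) or no low-count filter (0.0403). Il2ra (0.88, 0.0305), Cd27 (-0.54, 0.0225) and Tfrc (0.0478) passed without DCKO library 4. Tfrc passed also without DN3b library 4 (0.0322), Ptcra (0.64, 0.30) and Notch3 without DN3b library 1 (1.28, 0.0153 and 1.15, 0.0363), and Cdkn1b without DN3a library 1 (0.0475) or 2 (0.0370).

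Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), which encodes the cell cycle inhibitor p21, stood at 39.4 ± 13.6 CPM in DCKO against 4.14 ± 1.58 in DN3b and 16.0 ± 2.85 in DN3a (SD, n = 4), 9.46-fold above DN3b (log2 3.24 ± 0.31, adjusted p = 2.4e-05). Mdm2, which encodes the ubiquitin ligase of p53, was 2.13-fold above DN3b (1.09 ± 0.08, 5.1e-06), at 185 ± 12.6 against 86.8 ± 4.07. The p53 target list as a whole went both ways, with 7 genes up and 5 down of 27 (9 and 7 adjusted over the list alone; adjusted p = 0.783); Phlda3 was 2.56-fold lower. The DNA damage response and repair list had 0 genes up and 1 down of 30 (0 and 0 adjusted over the list alone; adjusted p = 0.739). That gene, Mdc1 (log2 -0.57, 0.042), lost the call without DN3a library 2, 3 or 4, DN3b library 2, 3 or 4, or DCKO library 1, 2 or 4 (0.0507 to 0.104), with limma-voom (0.0585) and with 8 libraries alone (0.0582). Of the G1 and S phase list 4 of 37 rose and 0 fell (3 adjusted over the list alone; adjusted p = 0.0872), with Ccne2 2.56-fold, E2f2 1.92-fold and Cdc25a 1.48-fold higher. This list passed without DN3a library 1 (0.0479) or 4 (0.0420), DN3b library 3 (0.0236) or 4 (0.00676), or DCKO library 2 (0.0408). Of the G2 and M phase list 0 rose and 1 fell of 30 (0 and 0 adjusted over the list alone; adjusted p = 0.635). That gene, Cdc25b (log2 -0.85, 0.048), lost the call without DN3a library 2 or 3, DN3b library 2, 3 or 4, or DCKO library 1, 2 or 3 (0.0591 to 0.124) and with limma-voom (0.0505).

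The recombinase genes Rag1 and Rag2 were 4.33-fold (log2 2.11 ± 0.37, adjusted p = 0.0019) and 2.44-fold (1.28 ± 0.27, 0.0061) above DN3b, and the end-joining genes Lig4 and Xrcc4 1.88-fold and 1.74-fold. Rag1 averaged 4310 ± 2120 CPM in DCKO, 997 ± 423 in DN3b and 1810 ± 501 in DN3a (SD, n = 4). The V(D)J recombination list had 4 genes up and 2 down of 14 (5 and 2 adjusted over the list alone). Camera did not call it (adjusted p = 0.201), while fry called it higher (adjusted p = 0.0218). T cell receptor beta segments (41 measured, GRCm38 chromosome 6, 40891229 to 41558452) had 10 genes up and 21 down (11 and 22 adjusted over the list alone) and differed by class, a division made after the values were seen. Of 23 V segments 21 fell and 0 rose (median log2 -4.35; Trbv1 -5.42 ± 0.31, Trbv29 -5.01 ± 0.34), of 14 J segments 9 rose and 0 fell (median 1.16), and of 2 constant regions neither passed (median 0.09). V segments summed to 114 ± 4.66 CPM in DN3a, 313 ± 81.2 in DN3b and 45.3 ± 5.89 in DCKO. J segments summed to 157 ± 41.3, 89.4 ± 39.5 and 243 ± 52.4, and constant regions to 1150 ± 62.9, 1680 ± 66.4 and 1730 ± 130 (SD, n = 4).

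**Figure D3:**
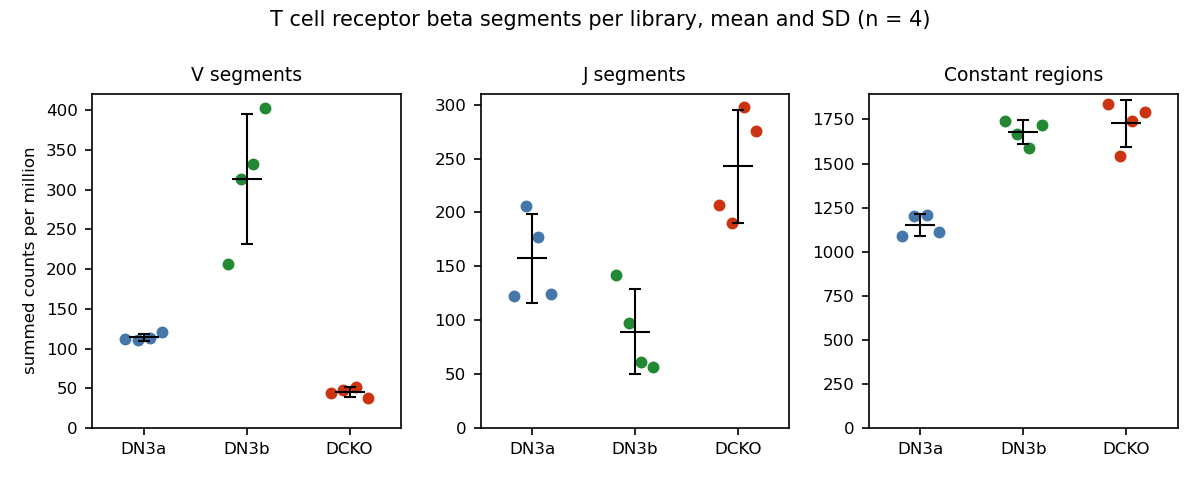
Summed CPM of T cell receptor beta V segments, J segments and constant regions in each library (points), with the mean and SD of each group (bars, n = 4); axes start at 0. In DCKO the V sums (37.6 to 51.3) lie below those of all control libraries and the J sums (190 to 298) above those of DN3b, whose highest is 142.

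Camera called 3 lists higher in DCKO than in DN3b, each lost with an estimated correlation: cholesterol synthesis (adjusted p = 0.678), interferon response (0.751) and early progenitor genes (0.678). Of 22 cholesterol synthesis genes 12 rose and 0 fell (12 and 2 adjusted over the list alone), among them Hsd17b7 (3.05-fold) and Insig1 (1.77-fold). Of 26 interferon response genes 10 rose and 0 fell (14 and 0 adjusted over the list alone), with Usp18 at 3.56-fold and Gbp3 at 2.03-fold; the list summed to 860 ± 42.1 CPM in DCKO, 562 ± 151 in DN3b and 1070 ± 79.9 in DN3a. Dendritic cell markers summed to 198 ± 13.8, 135 ± 32.6 and 172 ± 9.96 in the same groups, and myeloid markers to 54.2 ± 9.01, 49.1 ± 11.4 and 71.1 ± 2.38 (SD, n = 4). Of 15 early progenitor genes 4 rose and 0 fell (5 and 1 adjusted over the list alone), including Cd44 (4.51-fold), Flt3 (1.95-fold) and Hhex (5.45-fold, on 16 counts in the 4 DN3b libraries). Cdh5 (22.1-fold), the actin-severing protein gene Scin (10.8-fold), Ly6a (5.89-fold), Mllt11 (4.92-fold), Rapgef4 (4.36-fold) and Epsti1 (4.34-fold) were among the 8 largest rises, as was the mast cell protease gene Cpa3 (7.39-fold), whose adjusted p of 0.017 became 0.0512 without DN3b library 3. H2-Q2 (ENSMUSG00000091705, chromosome 17, 35342242 to 35346762), a nonclassical class I gene whose close relatives can share its reads, stood at 52.4 ± 35.2 CPM in DN3b, 0.792 ± 0.687 in DN3a and 0.0876 ± 0.0639 in DCKO, where the 4 libraries held 12 counts. Klhl4 was 7.54-fold lower (log2 -2.91 ± 0.73; -4.37 without DCKO library 3).

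Replication-dependent histones as a list were lower (median log2 -0.65, camera adjusted p = 0.00662), although 3 of 58 genes rose and 0 fell in the test of single genes (2 and 0 adjusted over the list alone); the 3 included Hist1h1t (3.90-fold) and Hist2h2be (1.94-fold). This call ended with fry (0.442), without DN3b library 1 (0.0614), DCKO library 1 (0.0788) or DCKO library 2 (0.0973), and with an estimated correlation (adjusted p = 0.932). Camera called 6 lists in all. Beta-selection activation genes (adjusted p = 1.63e-05) and T cell receptor beta segments (5.62e-06) also passed with an estimated correlation (adjusted p = 0.0158 and 0.0470). Interferon response (5.62e-06), cholesterol synthesis (3.59e-05) and early progenitor genes (0.0109) did not (adjusted p = 0.751, 0.678 and 0.678). Of 35 splits of the 8 libraries of a comparison, 10, 12 and 27 gave as many called lists as the real one in the order DN3b against DN3a, DCKO against DN3a and DCKO against DN3b. Splits that exchange a single library keep part of the real contrast, so these shares are not pure chance.

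**Figure D4:**
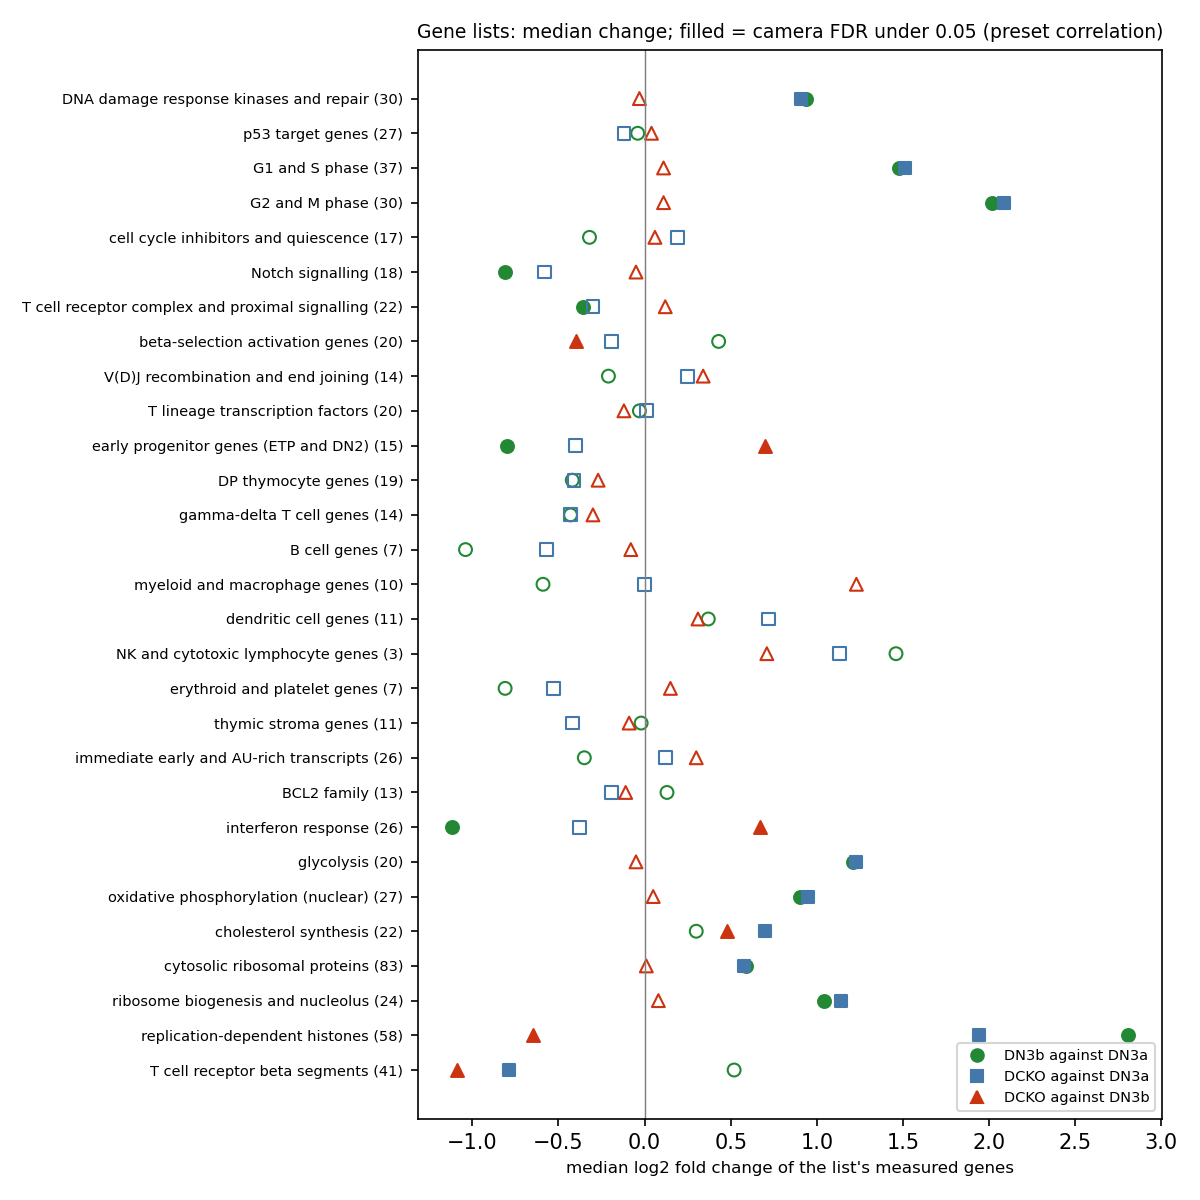
Median log2 fold change of the measured genes of each of the 29 lists (their number in brackets) in the 3 comparisons; filled symbols mark camera adjusted p under 0.05 with the preset correlation. In DCKO against DN3b the median of T cell receptor beta segments is -1.09 and that of beta-selection activation genes -0.40.

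The remaining lists missed the threshold with camera in this comparison. Members up and down, with the adjusted p, were 3 and 1 of 17 for cell cycle inhibitors (0.201), 2 and 2 of 18 for Notch signalling (0.969), 4 and 3 of 20 for T lineage transcription factors (0.837), 1 and 5 of 19 for genes of CD4 and CD8 expressing thymocytes (0.427), and 2 and 4 of 14 for gamma-delta T cell genes (0.174). Immediate early and AU-rich transcripts had 6 up and 4 down of 26 (0.586), the BCL2 family 1 and 3 of 13 (0.711), glycolysis 1 and 0 of 20 (0.586), oxidative phosphorylation 2 and 0 of 27 (0.275, or 0.0390 without DN3b library 4), ribosomal proteins 1 and 0 of 83 (0.781) and ribosome biogenesis 2 and 0 of 24 (0.467). Markers of other cells gave 1 up and 1 down of 7 for B cells (0.873), 1 and 0 of 10 for myeloid cells (0.0937), 2 and 1 of 11 for dendritic cells (0.326), 1 and 0 of 3 for cytotoxic lymphocytes (0.553), 0 and 0 of 7 for erythroid cells and platelets (0.586) and 1 and 1 of 11 for thymic stroma (0.586). Adjusted over the list alone, the counts were 0 and 0 for glycolysis, oxidative phosphorylation and ribosomal proteins, 1 and 0 for ribosome biogenesis and 4 and 0 for myeloid cells. They were 4 and 1 for cell cycle inhibitors, 3 and 2 for Notch signalling, 5 and 4 for T lineage factors and 7 and 4 for immediate early transcripts. The BCL2 family had 2 and 3, and CD4 and CD8 expressing thymocytes and gamma-delta T cells 2 and 6 each. Fry called these last 2 lists lower (adjusted p = 0.0305 and 0.0296) and cell cycle inhibitors higher (0.0441). The myeloid list passed without DN3b library 1 (0.0319), DCKO library 2 (0.0312) or DCKO library 3 (0.0345) and with upper quartile scaling (0.0497).

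In this comparison 2635 of 13944 genes passed, 1438 higher and 1197 lower in DCKO, 810 by at least 2-fold. Upper quartile scaling moved the median of all genes from -0.022 to -0.101 and the split to 1051 higher and 1644 lower. The count fell to 1670 without DN3b library 2, 1601 without DN3b library 3, 1730 without DCKO library 1 and 1654 without DCKO library 2, and to 950 without both of these DCKO libraries, a choice made after the data were seen. Without both, Ccne2 (log2 1.19, adjusted p = 0.0633), Rag2 (0.92, 0.105), Flt3 (0.73, 0.0621), Hhex (2.04, 0.0934), Cdc25a (0.54, 0.0602), Hist2h2be (0.89, 0.0572) Klhl4 (-2.06, 0.129), Mdc1 (-0.43, 0.282) and Cdc25b (-0.64, 0.339) no longer passed, while Rag1 moved from 2.11 to 1.38 and Gbp3 from 1.02 to 0.55 and both passed. The authors' deposited tables of DESeq2 results called 3884 genes higher and 3873 lower in DN3b against DN3a, 4345 and 4366 in DCKO against DN3a, and 1598 and 1442 in DCKO against DN3b. Of the genes called here, 7091, 8082 and 2538 were called in the authors' deposited tables with the same direction and 0 with the opposite one.

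On the axis from DN3a (0) to DN3b (1), over the genes that separate these control groups, DCKO stood at 0.953 ± 0.108 (SD over 4 DCKO libraries). Each of the 6 ways to choose genes on 2 replicate numbers and place DCKO with the others gave 0.842 to 1.16, from 43 to 2072 genes. The values divided by replicate number 1 of the control groups. Placing without it gave 0.842 to 0.91, and placing with it gave 0.996 to 1.16. The SD over DCKO libraries does not cover this difference, so a position level with DN3b is not settled. Genes that rise from DN3a to DN3b gave 0.951 (0.853 to 1.09 over the 6 choices) and genes that fall gave 0.995 (0.645 to 1.33, from 8 to 1065 genes). In simulated groups placed at 0, 0.5 and 1 the measure returned 0.003, 0.504 and 1.003.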

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

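The tests of T cell receptor beta segments, H2-Q2 and the interferon list were chosen after those results were seen. Of 378 sets of 4 replicate values, 16 (4.23%) held a library far from the other 3 by Dixon's test, where chance gives about 1 in 20. In DN3a library 1, Cdh23 (117 CPM), Hsd11b1 (48.1) and Zfp36 (2.42) were high and Fancd2 (12.5) was low. In DN3a library 2, E2f2 was low at 57.4 CPM and Gm42418 took a high share of counts, 0.0395%, and in DN3a library 4 Gbp3 was high at 34.0. In DN3b library 1, Klhl4 (5.86 CPM), Notch1 (1420), Ptcra (129) and Rag1 (1630) were high, and Cdc25b (37.4), Fancd2 (40.5) and Mdc1 (41.8) were low. More flagged values fell in this library than in any other, so they are not spread evenly. Klhl4, Notch1, Ptcra, Rag1 and Fancd2 lay there on the side of DN3a. Of the DN3b libraries it was also nearest to DN3a on the first principal component (-8.02). It had the lowest T cell receptor beta V sum (206 CPM) and the highest J sum (142) of that group. In DCKO library 3, Hist2h2be was low at 20.6 CPM. In DCKO library 2, Lars2 took 0.569% of the counts against 0.00306% or less in the other DCKO libraries.

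T cell receptor beta V segments were lower, and J segments higher, in DCKO than in DN3b. A lower yield of the whole locus is argued against by the constant regions, whose median log2 fold change was 0.09 with neither past the threshold. A mixture of DN3a and DN3b cells is argued against by the V sums, which reached at most 51.3 CPM in DCKO against at least 111 in every control library. A candidate explanation is that fewer DCKO cells carry a rearranged beta gene: the lowest J sum in DCKO was 190 CPM against a highest of 142 in DN3b, which leaves open how the J reads arise. No reads were examined, so rearranged transcripts were not counted.

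H2-Q2 was detected mainly in DN3b, and its neighbour H2-Q1 moved with it (log2 5.38 ± 0.67, DN3b against DN3a). Reads shared with the abundant class I genes are argued against: 7 of these had a median of -0.67 in the same comparison. DN3b lay above DN3a in 4 of 4 paired numbers. This counts against a variant between the control animals only if libraries of a number share a mouse. The labels do not state that, so such a variant stays open. The low level in DCKO (at most 0.139 CPM) lies below the lowest DN3a level (0.236) as well and cannot be told apart from a variant carried by the DCKO animals, since genotype and group coincide.

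The interferon response list summed to 298 ± 78.3 (SE) CPM more in DCKO than in DN3b; 10 of 26 genes passed, and the call was lost with an estimated correlation (adjusted p = 0.751). RNA from myeloid or dendritic cells, which the sort should remove, cannot be told apart from this, since the ratio of their markers to interferon transcripts in such cells was not measured. Their markers (10 of 20 and 11 of 16 measured here) gained 67.3 ± 24.3 together. Most of this gain came from Bst2, which stands in both the dendritic and the interferon list. Bst2 averaged 114 ± 10.9 in DCKO and 64.2 ± 28.5 in DN3b. Lyz2 stood at 9.26 ± 3.53 in DCKO and 4.25 ± 3.79 in DN3b, and Cd74 at 2.21 ± 1.29 and 1.80 ± 0.363. A response above that of both control groups is argued against for the list as a whole, whose highest DCKO sum, 904, lay below the lowest DN3a sum, 989, with 3 members up and 9 down against DN3a, but stays open for 2 of 26 members, Bst2 and Usp18 (68.4 ± 8.1 in DCKO, 25.5 ± 5.87 in DN3a), too few to decide.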

How the results depend on the processing

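The fit of the 8 control libraries with a block, and the fits without DCKO libraries 1 and 2 and without DN3b library 1 and DN3a library 4 (picked by their place on the first principal component), were chosen after the data were seen; the last gave 7561 genes for DN3b against DN3a. No result that passed the threshold in the main run or in an alternative had opposite directions in the 2 runs. Changes of sign between runs that both missed the threshold were not counted as reversals. Gene counts for DCKO against DN3b were 1157 at an FDR of 0.01, which is stricter by construction, and 950 without DCKO libraries 1 and 2, where fewer libraries remain. Leaving out each library gave 6253 to 7790 genes for DN3b against DN3a, 7622 to 8699 for DCKO against DN3a and 1601 to 3249 for DCKO against DN3b, and 12 to 13, 10 to 12 and 5 to 8 gene lists. With an estimated correlation 0, 0 and 2 lists passed in these comparisons, and fry called 18 lists for DCKO against DN3a; the cause was not tested. The nonamer UUAUUUAUU in place of UAUUUAU gave an odds ratio of 0.883 for genes lower in DCKO than in DN3a (permutation p = 0.15); over that result's alternatives p ran from 0.00028 to 0.15. Replicate number as a block in all 12 libraries gave 7537, 8556 and 2793 genes, and the Notch list then passed for DCKO against DN3a (0.033), though DCKO numbers do not pair with those of the controls. In the paired fit of the control libraries Zfp36l2, Rag1 and Trp53 gained a call and no other named gene or list changed. The position of DCKO ran from 0.918 to 0.987 over the settings tried and without each DCKO library, but from 0.842 to 1.16 over the 6 choices of genes and from 0.862 to 1.10 over single DCKO libraries. Of 154 gene results past the threshold, 11 lost it without at least 1 library, and of 32 others 16 gained it; of 28 list results 1 lost it and of 59 others 7 gained it. Removing the most abundant features also removed receptor genes, so the T cell receptor beta list has no value there. Depth limits genes with few counts in a group, such as H2-Q2 in DCKO (12 counts in 4 libraries), and Cd34 (4) and Hhex (16) in DN3b.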

Other observations

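The gamma segments and the test of genes beyond both control groups were chosen after results were seen; the tests of UAUUUAU and of other splits were chosen before. The V segments of the T cell receptor gamma locus also differed. Against DN3a, 6 of 7 measured gamma V segments fell in DN3b (median log2 -1.22) and 6 of 7 fell in DCKO (median -3.62). Against DN3b, 5 of 7 fell in DCKO (median -2.59), with Trgv2 at -2.59 ± 0.19 and Tcrg-V4 at -3.75 ± 0.20, while Tcrg-V5 (1.16, adjusted p = 0.13) and Tcrg-V6 (-1.17, 0.13) missed the threshold.

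Other splits of the 8 libraries of each comparison, 35 with the real one, were fitted in the same way with edgeR. In each comparison only the real split (1 of 35) reached its number of genes. That number was 7334 for DN3b against DN3a, 8391 for DCKO against DN3a and 2635 for DCKO against DN3b. The share is under 0.05 but is the smallest that 35 splits can give. It argues against chance for the counts of the DCKO comparisons, each taken alone. Every other split holds libraries of both groups on each side, which widens the spread, so a low count there is partly built in. For DN3b against DN3a the share decides nothing, because the paired control libraries have only 8 splits that part all pairs. That is too few for a share under 0.05. Among these the real one gave 7334 genes and 12 lists and the highest other 0 and 15. The highest of all other splits called 0 genes at the FDR, and at an unadjusted p under 0.05 the highest called 4962, 3394 and 4061 against 8170, 8967 and 4713 in the real splits. For the number of lists that camera called with the preset correlation, chance cannot be excluded: 10, 12 and 27 of 35 splits gave as many as the real 12, 10 and 6, and the highest other splits gave 15, 14 and 16. Splits that exchange a single library between the groups keep part of the real contrast. In DCKO against DN3a every other split with 10 or more lists was of this kind. So were most others with 12 or more in DN3b against DN3a. In these comparisons the shares cannot decide.

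Zfp36 family proteins bind UAUUUAU, so the hypothesis was that transcripts with this heptamer in the 3 prime UTR rise in DCKO. Of 13944 genes 11678 (83.7%) had a 3 prime UTR to search. Among the 1376 genes higher in DCKO than in DN3b 54.7% held the heptamer, against 37.0% expected from UTR length, with an odds ratio of 2.85 (95% interval 2.51 to 3.25; permutation p = 1e-05, the smallest the permutations can give). It ranked 1 of 21 arrangements of the same letters, whose others had odds ratios of 1.57 to 2.61, so each arrangement had an odds ratio above 1. Genes lower in DCKO than in DN3b had an odds ratio of 0.594, rank 14 of 21 with arrangements from 0.534 to 0.763, so this depletion is not particular to the heptamer. Against DN3a the odds ratio for higher genes was 1.31, rank 8 of 21 with others up to 1.46, which leaves the hypothesis open in that comparison. A direct effect on some of these transcripts is a candidate explanation for the enrichment against DN3b, but binding was not measured. The heptamer was not tested between DN3b and DN3a, so a stage difference in such transcripts cannot be told apart from it. The highest other arrangement, AUUUAUU at 2.61, lay within the interval of the heptamer. It and UUAUUUA (2.22) are the heptamer shifted by 1 base, and both lie within UUAUUUAUU, so they are not independent controls. The remaining arrangements had odds ratios of at most 1.84. The nonamer UUAUUUAUU gave an odds ratio of 2.32 (95% interval 1.97 to 2.74) for genes higher than in DN3b.

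A mixture of DN3a and DN3b cells would place the mean of no gene beyond both. A mixture as the whole account of DCKO is argued against by genes for which all 4 DCKO libraries lay beyond all 8 control libraries. There were 988 above and 770 below, 1758 together. Chance gives a mixture at most 199 in each direction, although genes are not independent. A difference in animals or preparation shared by the DCKO libraries would place genes beyond both as well. It cannot be told apart from an effect of genotype, since genotype and group coincide. By the test of single genes 985 lay above both control groups and 802 below, against 441 and 353 expected of independent lists, and at most 2 and 5 in 25 simulated mixtures. Sets simulated with no differences decide nothing about a mixture, since few genes can pass the FDR in them: 20 sets gave at most 0 and 1, and at an unadjusted p under 0.05 45 to 78 and 59 to 101, against 1525 and 1506 in the data. With different DCKO libraries in the 2 comparisons, 177 to 565 genes lay above both, where independent lists give 55 to 238, and 106 to 407 below both, where they give 34 to 232.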
